A study of Pimephales promelas with 112 samples.

How the data were processed

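Expression was measured on one-colour Agilent arrays, each with the RNA of a pair of whole larvae. Per the labels' protocols, larvae were held in small mesh-ended vessels, each inside a 10 L flow-through tank, and 3 tanks were run per concentration. RNA was labelled with Cy3 together with spike-in RNA. The scanner files were deposited as intensity values, made with Agilent Feature Extraction 11.0.1.1 and protocol GE1_1100_Jul11 from a G2505C scanner, per the file headers. The processed intensity is background-subtracted and spatially detrended and is not normalized between arrays, per the file headers. The authors also deposited a table of log2 values for the same arrays, without a stated tool. All its columns have the median 7.82, so its arrays were put on a common scale. Equal medians alone do not tell quantile normalization from median scaling. Each column was closest to its own array's scanner values (correlation 0.941 or higher, median 0.980), with slopes from 0.699 to 1.34, so values rise with signal on a log2 scale, and the background step stays unknown. Flags for background, saturation and outlier spots are other values of the software, per the file headers.

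The main analysis used log2 of the processed signal minus each array's 75th percentile of it. Control spots and spots marked as outliers by the software were left out and the spots of each probe were averaged, from 61053 spots other than controls. A probe was kept where it was well above background in at least 0.5 of the arrays of at least 1 group. That left 43883 probes, of which 7 lacked a value in a tank, and 43876 were tested. The 14 arrays with a failed check in the labels were left out. Arrays of a tank were averaged, with 1 to 5 arrays per tank, because larvae of a tank shared their water.

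Tank means were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend), 1 fit over all 12 groups with 21 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05, and "called" means past it. Contrasts were each concentration and the mean of both against the control of the same experiment, the concentrations against each other, the mean of the 4 chemicals, and differences between chemicals. An F test compared the carrier controls. The tests, the alternatives and the rule for named items were chosen before the data were examined, except where stated. The groups, replicate numbers, vessels, measured concentrations and deaths come from the labels. The p-values rest on a spread between tanks that was pooled over the 12 groups of all experiments, each of which was run once. The consensus correlation of arrays of a tank was 0.0204, so a mean of few arrays is less precise. The main fit did not weight tanks by their arrays.

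The classifier was a diagonal linear discriminant on the 50 probes with the largest moderated statistic among the training arrays, scored as the area under the ROC curve over tanks, with tank labels permuted within experiments in 100 draws. Agreement between chemicals was the correlation of mean changes across probes under the same relabelling. Unchanged groups against shared controls were simulated from the fitted spread in 20 draws, with every probe drawn independently. The fit was tested on simulated data of 43700 probes, 200 of them changed. Of changes of 1 on the log2 scale it recovered 71.6% for the bifenthrin mean and 83.6% for the mean of the chemicals. Of changes of 0.5 it recovered 26.9% and 71.6%. Where many more probes change the threshold is easier to reach, so these shares do not carry over.

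Signal over background limits what the arrays show: 45.9% to 91.3% of probes were well above background on an array, the 75th percentile of processed signal ranged from 358 to 2200, and at most 13 spots were saturated. Slides held 8 arrays each, 14 in all, scanned on 3 days, and mixed groups. Over all 6216 pairs of arrays the differences had an SD of at least 0.48 on the log2 scale (median 0.79), so no array duplicated another.

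Alternatives were inclusion of arrays with failed checks, quantile normalization, normexp background correction with an offset of 50, the authors' table, no and a stricter filter on dim probes, arrays in place of tanks with and without the tank as a random block, the slide or the replicate number as a block, weights, each experiment alone, deaths as a covariate, slopes on measured concentration, and leaving out each tank. The mean spot signal is not a column of the scanner files used here, so normexp took the median signal. Probe identifiers could not be paired with gene names through the tables used here, so the gene lists, tissue markers and named genes planned beforehand were not analysed here. The rule for named genes (past the threshold and of the same sign in every chemical, ordered by change) was applied to probes of the mean over chemicals, and up to 2 that rose and 2 that fell are named. Other software was the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.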

Results

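Larvae of the fathead minnow (Pimephales promelas), a small freshwater fish kept for toxicity testing, were exposed for 48 h from about 48 h after hatching to 1 of 4 pyrethroids. Pyrethroids are insecticides that hold voltage-gated sodium channels open. Bifenthrin, cypermethrin, esfenvalerate and permethrin were each tested in a separate experiment with its own carrier control of 0.002% DMSO. Per the labels an experiment had 8 concentrations. The series holds arrays of the control and of 2 nominal concentrations per experiment, chosen below the median lethal concentration per the labels. The series was made to find transcripts that mark pyrethroid exposure and to build a classifier from them. RNA from pairs of whole larvae was hybridised to one-colour arrays, and the 98 arrays with no failed check in the labels entered the comparisons. They fell into 12 groups and 33 tanks. The tank was the replicate, with 3 tanks in most groups, 2 for esfenvalerate at 0.5 µg/L and 1 for esfenvalerate at 1 µg/L. On the median array 81.8% of probes were well above background, with a range of 45.9% to 91.3%. The number of tanks and arrays limits the precision. Probes carried identifiers of assembled sequences without gene names, so changes are given by probe.

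Measured concentrations were well below nominal, and permethrin was measured in the carrier controls of its experiment, from contamination or from background of the chemical assay, which the labels used here do not settle. Bifenthrin measured 0.0252 ± 0.00127 µg/L at 0.148 µg/L nominal and 0.0439 ± 0.0124 µg/L at 0.297 µg/L nominal (SD, n = 3 tanks each), 17.1% and 14.8% of nominal. Cypermethrin measured 0.201 ± 0.020 µg/L at 0.5 µg/L and 0.344 ± 0.016 µg/L at 1 µg/L (SD, n = 3 tanks each). Esfenvalerate measured 0.0603 ± 0.00478 µg/L at 0.5 µg/L (SD, n = 2 tanks) and 0.203 µg/L in the 1 tank at 1 µg/L. Permethrin measured 0.622 ± 0.0164 µg/L at 1.56 µg/L, 0.972 ± 0.0714 µg/L at 3.125 µg/L and 0.0863 ± 0.00931 µg/L in the carrier controls (SD, n = 3 tanks each). The other 3 sets of controls measured 0 µg/L. At cypermethrin 1 µg/L 8 of 31 larvae died, with 45.5% dead in 1 vessel, against 1 of 30 in its control. At permethrin 3.125 µg/L 4 of 28 died, against 0 of 29. No difference in deaths per tank passed the threshold (exact permutation test, p = 0.2 and 0.1 for these 2, adjusted p = 0.8 for both over 8 comparisons), and 3 tanks against 3 cannot give a p below 0.1.

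**Figure D1:**
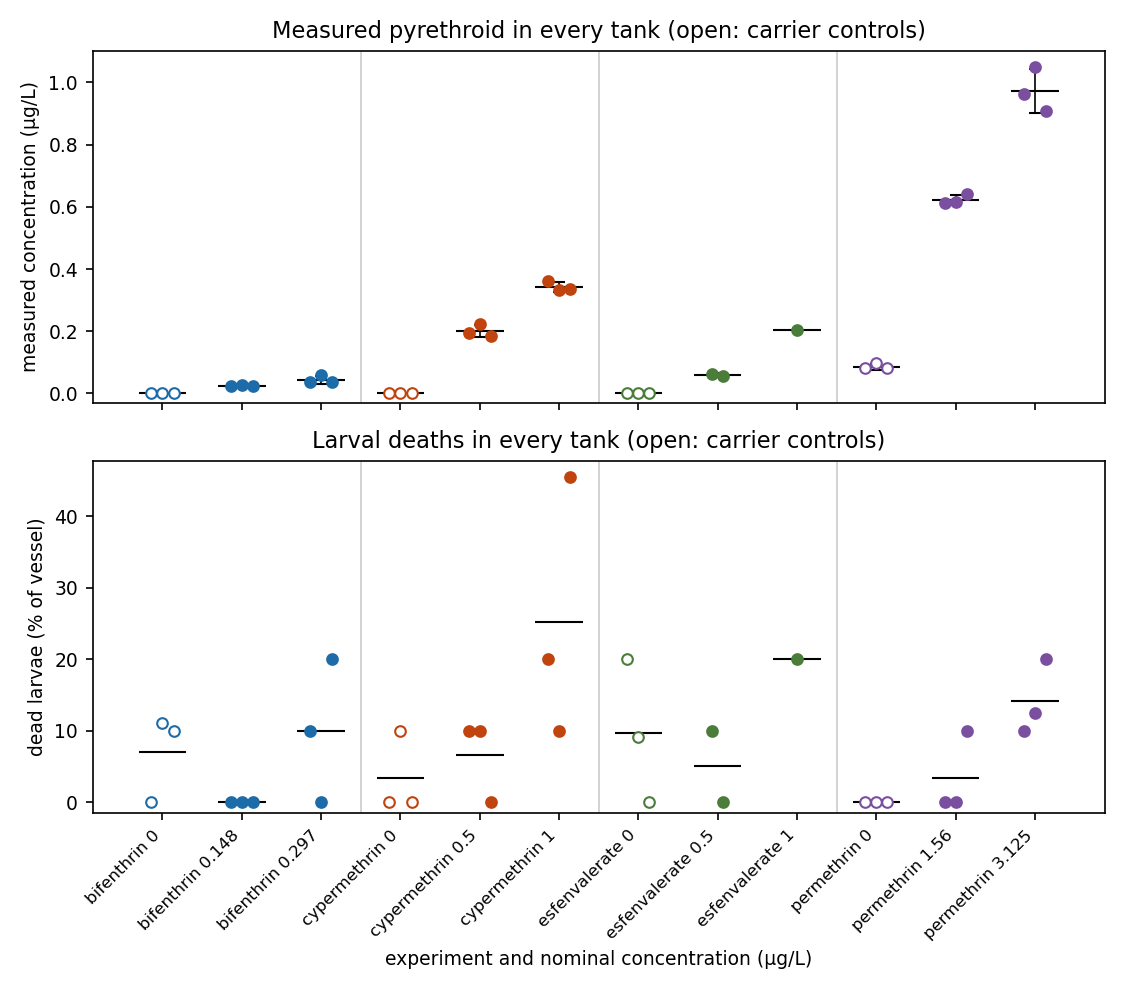
Measured pyrethroid (µg/L) and dead larvae (% of the vessel) in each of the 33 tanks, by experiment and nominal concentration. Points are tanks, open for carrier controls, lines are means and bars in the upper panel are SD; the permethrin controls lie near 0.0863 µg/L and the other controls at 0.

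Tanks at bifenthrin 0.297 µg/L differed from their controls at 13267 of the 43876 probes tested, 4371 higher and 8896 lower. This is a difference between groups, in which exposure cannot be told apart from a batch that followed whole groups. The median size of a called change was 0.69 on the log2 scale, and 1366 probes rose and 1132 fell by more than 2-fold. At 0.148 µg/L no probe passed limma's test, although 8673 reached an unadjusted p under 0.05 where chance gives 2194. The concentrations themselves differed at 3556 probes, and the mean of both differed from the control at 9264, 2956 higher and 6308 lower. With the tank's spike-in level as a covariate, added after seeing the data, these 9264 became 1076 and the 13267 became 6700. Spike-in RNA, relative to the array's 75th percentile, stood at -1.06 ± 0.53 in control tanks and -1.68 ± 0.17 in exposed tanks (SD, n = 3 and 6, exact permutation p = 0.0119, adjusted p = 0.0476 over the 4 chemicals). Control vessel 12, with 1 array, stood at -0.458 and the other controls at -1.40 and -1.33.

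A fit of arrays with the tank as a random block called 13775 probes at bifenthrin 0.297 µg/L without and 14858 with the slide as a further block. The median change of all probes was -0.16 at 0.297 µg/L, and -0.057 after quantile normalization, under which 44.7% rather than 32.9% of called probes were higher. Normexp background correction moved the median to -0.24 here, to -0.25 at 0.148 µg/L and to -0.16 at cypermethrin 0.5 µg/L, where it was 0.0029, and with it 8512 probes were called at 0.148 µg/L. Without control vessel 12, which had 1 array, 6515 probes were called at 0.297 µg/L and 633 for the mean of both concentrations. Without vessel 5 of the 0.297 µg/L group the counts were 7888 and 6054, and without vessel 14 of the 0.148 µg/L group the mean gave 6149. Arrays with failed checks included, the counts were 5213 and 1744. Without control vessel 17 or 9, 1579 or 25 probes were called at 0.148 µg/L. The 3556 fell to 1184 and 1462 without vessels 19 and 25 of the lower and to 1446 and 2025 without vessels 5 and 26 of the higher concentration. It rose to 8362 in fits of arrays with the tank as a random block. It fell to 695 with arrays of failed checks included and to 1656 with normexp.

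**Figure D2:**
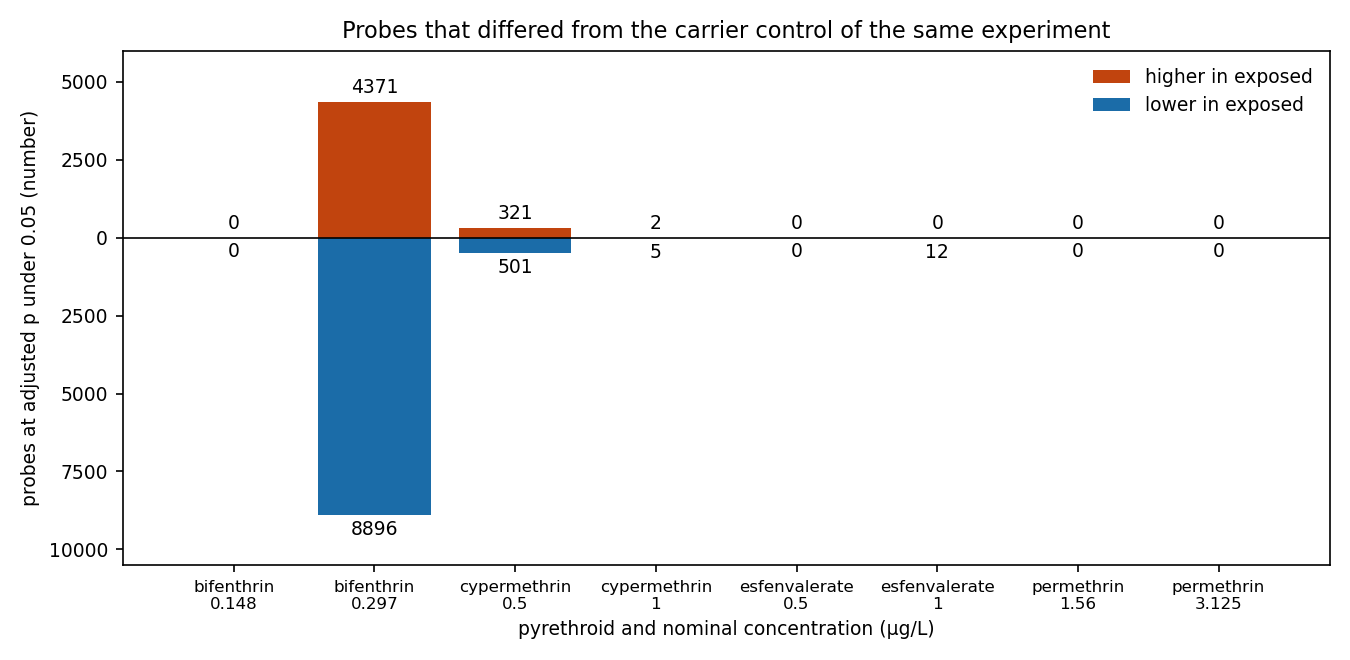
Number of probes at adjusted p under 0.05 (limma) that were higher, drawn upwards, or lower, drawn downwards, than the carrier control of the same experiment, for each pyrethroid and nominal concentration (µg/L). At bifenthrin 0.297 µg/L 4371 and 8896 probes differed and at cypermethrin 0.5 µg/L 321 and 501. No other concentration differed at more than 12.

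In the cypermethrin experiment more probes differed from the control at the lower than at the higher concentration. As for bifenthrin, exposure cannot be told apart here from a batch that followed whole groups. At 0.5 µg/L 822 probes were called, 321 higher and 501 lower, with a median size of 0.79 on the log2 scale. At 1 µg/L, where measured cypermethrin was 1.71 times higher, 7 were called, 2 higher and 5 lower. The concentrations differed from each other at 1233 probes, of which 744 were higher at 1 µg/L, but 207 differed with arrays of failed checks included, 95 in the experiment fitted alone and 429 with deaths as a covariate, 39.6% of them higher rather than 60.3%. Fits of arrays with the tank as a random block gave 3630. The mean of both concentrations differed from the control at 31 probes, at 1892 with arrays of failed checks included, at 181 with normexp and at 0 in the experiment fitted alone. A fit of arrays with the tank as a random block called 1986 at 0.5 µg/L without and 2657 with the slide as a further block. Of the 822, 39.1% were higher, and of those called with normexp 10.1%. Fitted on the cypermethrin experiment alone, the count at 0.5 µg/L was 42. It was 430, 417 and 350 without vessels 14, 19 and 25 of that group, and the 1233 became 775, 622 and 412, or 735 and 783 without vessels 23 and 26 of the 1 µg/L group. At 1 µg/L leaving out control vessel 12 raised the 7 to 107, control vessel 9 left 1, and control vessel 17 or exposed vessel 26 left 0. The 31 became 168, 15 and 10 without control vessels 12, 9 and 17, and 13 without vessel 14.

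Most of the probes that differed at cypermethrin 0.5 µg/L were also among the larger set that differed at bifenthrin 0.297 µg/L. Of the 822 called at cypermethrin 0.5 µg/L, 137 also rose and 465 also fell among the 13267 of bifenthrin 0.297 µg/L, against 32.0 and 102 for independent lists, and 0 went the opposite way. These comparisons have no tank in common. The difference between the changes passed the test at 55 probes, 2 of them among the 602 shared, and 7247 had an unadjusted p under 0.05. The shared probes, examined in the other groups after the results were seen, stood in the carrier controls of the esfenvalerate and permethrin experiments at the level of the changed groups. Signed by direction and centred per probe, their mean level was -0.68 ± 0.057 in bifenthrin controls, -0.53 ± 0.083 at bifenthrin 0.148 µg/L, -0.47 ± 0.020 in cypermethrin controls and -0.38 ± 0.073 at cypermethrin 1 µg/L. It was 0.28 ± 0.039 at bifenthrin 0.297 µg/L, 0.38 ± 0.041 at cypermethrin 0.5 µg/L, 0.33 ± 0.040 in esfenvalerate controls and 0.20 ± 0.027 in permethrin controls (SD, n = 3 tanks each). Esfenvalerate and permethrin exposure groups had means from 0.15 to 0.27. The controls and the changed groups of the bifenthrin and cypermethrin experiments chose these probes, so their separation was fixed. Among groups that did not, the 18 arrays of bifenthrin 0.148 and cypermethrin 1 µg/L ranged from -0.69 to -0.16 and the 46 arrays of the esfenvalerate and permethrin experiments from -0.033 to 0.54.

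**Figure D3:**
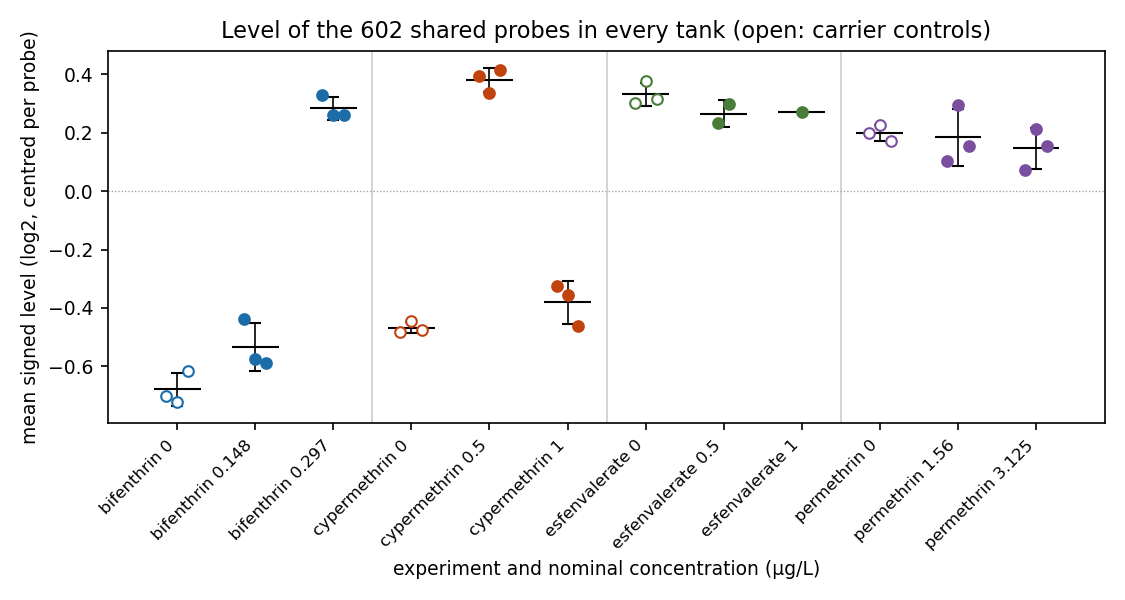
Mean level of the 602 probes called in the same direction at bifenthrin 0.297 and cypermethrin 0.5 µg/L, in each tank (log2, each probe centred on its mean over groups and signed by its direction), by experiment and nominal concentration in µg/L. Points are tanks, open for carrier controls, with mean and SD; esfenvalerate controls at 0.33 and permethrin controls at 0.20 lie with the changed groups, and bifenthrin 0.148 and cypermethrin 1 µg/L at -0.53 and -0.38 lie with their own controls.

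Few probes differed from the control in the esfenvalerate experiment. At 1 µg/L 12 probes were lower than in the control and none was higher, with a median size of 2.38 on the log2 scale. That group is 1 tank, assumed to vary like the other groups. At 0.5 µg/L limma called 0 probes, with 1382 at an unadjusted p under 0.05, and the mean of both concentrations gave 4, all lower. Of the probes called at 1 µg/L in alternatives, 3.7% of 27 were higher after quantile normalization, 0 of 4 after normexp and 47.6% of 21 with the values of the authors. In fits of arrays with tanks ignored or with the tank as a random block 2 were called, both higher. Whether probes called higher in an alternative are among the 12 was not examined, so these counts do not settle the direction. Without replicate 1, 2 or 3 of the 1 µg/L tank the 12 became 5, 132 or 69, and without control vessel 9 or 17 it became 4. The 4 became 15 without control vessel 12 or replicate 2, 11 without replicate 3, 2 without vessel 18 of the 0.5 µg/L group, and 0 without control vessel 9 or 17, vessel 10 of the 0.5 µg/L group or replicate 1. At 0.5 µg/L 1 and 3 were called without control vessel 12 and exposed vessel 10. Simulated changes of 1 on the log2 scale were recovered for 26.9% of probes at esfenvalerate 1 µg/L and for 58.2% at bifenthrin 0.297 µg/L. Only 200 of 43700 probes were changed there. With 13267 called the threshold is easier to reach, so the 58.2% does not carry over to the real bifenthrin comparison.

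No probe differed past the threshold in the permethrin experiment. Limma called 0 at 1.56 µg/L, at 3.125 µg/L, for their mean and for their difference, with 2688, 3211, 3543 and 1476 at an unadjusted p under 0.05. Measured permethrin in the exposed tanks was 7.21-fold and 11.3-fold that measured in the controls, if the control values are permethrin and not assay background. Treated as arrays with the tank as a random block, 389 probes passed for the mean of both concentrations.

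Cypermethrin and esfenvalerate carry an alpha-cyano group, which bifenthrin and permethrin lack, and both were tested at 0.5 and 1 µg/L nominal. At 0.5 µg/L their changes differed at 68 probes, 22 with the larger value under cypermethrin and 46 under esfenvalerate, with a median standard error of 0.30 for the difference. At 1 µg/L they differed at 8 probes, 7 with the larger value under cypermethrin and 1 under esfenvalerate, with a median standard error of 0.35. The 1 tank of esfenvalerate there is assumed to vary like the other groups, and leaving out its arrays was not tried for the 8. Over both concentrations 5 probes differed, all with the larger value under cypermethrin and by a median of 2.29 on the log2 scale. Leaving out 1 tank or array moved the 5 to between 3 and 53, the latter without cypermethrin control vessel 9. Fits of arrays with the tank as a random block, with or without the slide or replicate number as a further block, called 0, and with tanks ignored 20 were called, 40% of them higher. Measured cypermethrin was 0.201 and 0.344 µg/L and measured esfenvalerate 0.0603 and 0.203 µg/L, so the doses reached were not equal. The alpha-cyano pair minus the others gave 0 probes in limma, with 3421 at an unadjusted p under 0.05 and a median standard error of 0.18. Doses of bifenthrin and permethrin differ from these and were set by their own toxicity, so no equal-dose comparison could be made. Bifenthrin's mean change differed from that of permethrin at 6489 probes, of esfenvalerate at 717 and of cypermethrin at 38. Cypermethrin and permethrin differed at 8 probes and esfenvalerate and permethrin at 0, with 2759 at an unadjusted p under 0.05.

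Averaged over the 4 pyrethroids, 21 probes differed from the carrier controls, 7 higher and 14 lower, and 8 of them had the same sign in every chemical. The highest were SINGLET_6057 and UF_Ppr_AF_100015, whose tank values never differed from each other by more than 0.14. The mean change of SINGLET_6057 was 1.04 ± 0.18 on the log2 scale (SE, adjusted p = 0.0284), but it came from 2 concentrations. It was 3.05 ± 0.39 at bifenthrin 0.297 µg/L (adjusted p = 1.34e-05) and 3.25 ± 0.39 at cypermethrin 0.5 µg/L (adjusted p = 2.37e-05), in each case with all 3 exposed tanks above all 3 controls. Elsewhere it lay between 0.21 and 0.49, with no adjusted p under 0.48. Cypermethrin control vessel 9, with 1 array, stood at -2.24 and the other 2 controls at 0.19 and 0.53. Without it SINGLET_6057 changed by 2.39 at cypermethrin 0.5 µg/L, 5.23-fold rather than 9.53-fold, and by -0.39 at 1 µg/L. Its level was -0.20 ± 0.045 in bifenthrin controls and -0.50 ± 1.51 in cypermethrin controls, and 2.61 ± 0.083 in esfenvalerate controls and 1.88 ± 0.13 in permethrin controls (SD, n = 3 tanks each). SINGLET_12718 changed by -0.42 on average (SE 0.080, adjusted p = 0.0391), by -1.37 at bifenthrin 0.297 µg/L and by -0.91 at cypermethrin 0.5 µg/L. Its average passed the threshold in only 21 of 50 alternatives. UF_Ppr_AF_115657 fell by 0.42 as well (SE 0.079, adjusted p = 0.0326), and passed in 29 of 50 alternatives. Without bifenthrin 0.297 µg/L and cypermethrin 0.5 µg/L, an alternative chosen after seeing the data, 0 probes passed. The 21 became 156 without bifenthrin control vessel 17, 55 without cypermethrin control vessel 12, 52 without replicate 3 of esfenvalerate 1 µg/L and 32 without vessel 26 of cypermethrin 1 µg/L. It became 1 without esfenvalerate control vessel 9 or 17, 2 and 7 without bifenthrin control vessels 9 and 12, and 7 and 10 without permethrin control vessels 12 and 17. It became 13 without cypermethrin control vessel 17 and 9 without either tank of esfenvalerate 0.5 µg/L. The shares of 7 higher and 14 lower also moved with scaling: 53.8% of those called after quantile normalization were higher, and 14.3% after normexp.

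**Figure D4:**
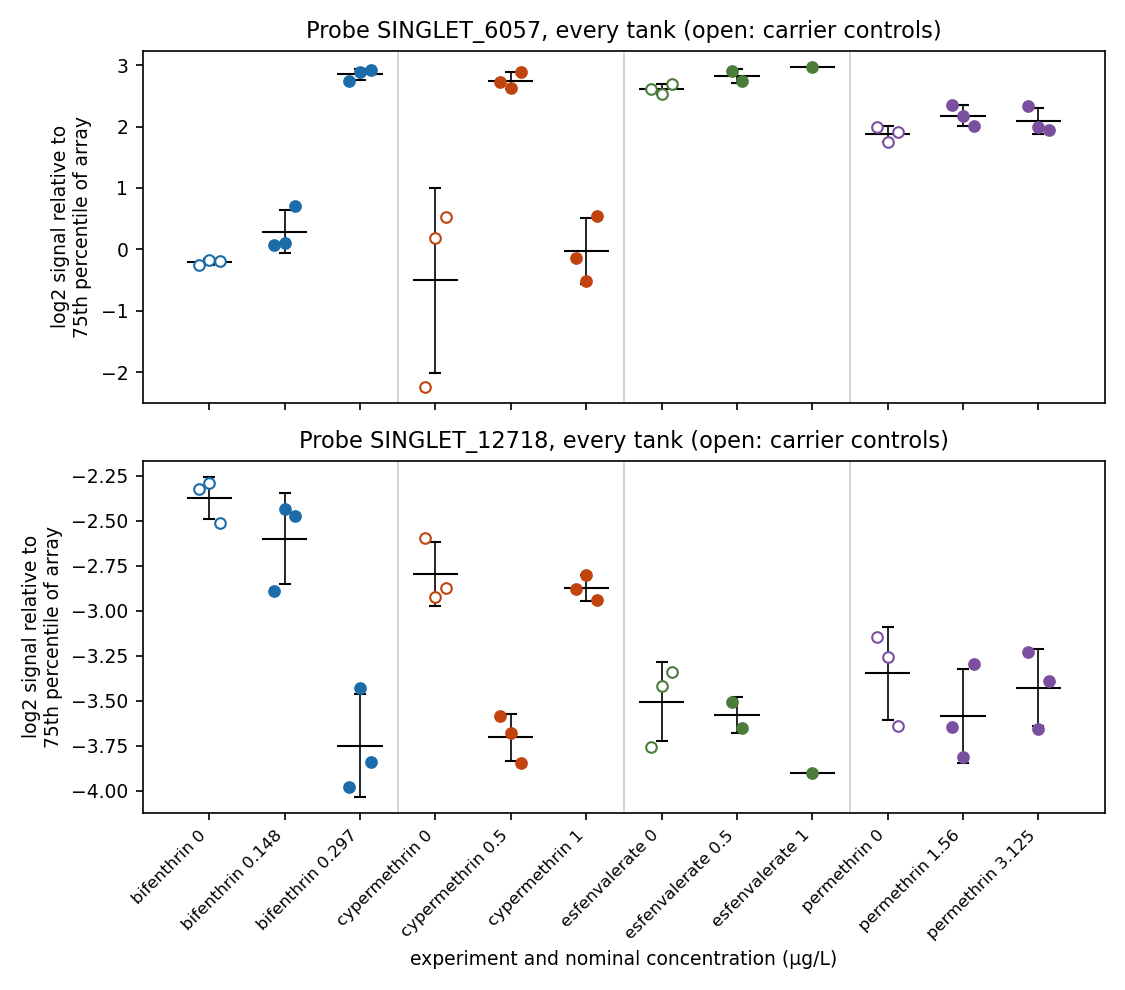
Level of probes SINGLET_6057 and SINGLET_12718 in each tank (log2 signal relative to the array's 75th percentile), by experiment and nominal concentration in µg/L. Points are tanks, open for carrier controls, with mean and SD; SINGLET_6057 lies at 2.85 at bifenthrin 0.297 µg/L and at 2.61 in the esfenvalerate controls.

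The carrier controls differed between experiments at 26569 probes, 60.6% of those tested. Bifenthrin controls differed from cypermethrin controls at 18014 and from esfenvalerate controls at 18578 probes with 0 µg/L measured in each, so arrays of unexposed larvae differed between experiments, whether through the larvae or the handling of RNA. From permethrin controls they differed at 23619. Pairs without the bifenthrin controls differed at far fewer probes. Cypermethrin and esfenvalerate controls differed at 2994, cypermethrin and permethrin controls at 2100, and esfenvalerate and permethrin controls at 4939. By these counts the bifenthrin controls stood furthest from the rest. Each chemical was tested in 1 experiment, so a difference between the effects of chemicals cannot be told apart from one between experiments. Across probes, which are not independent replicates, the mean changes of bifenthrin and permethrin ran in opposite directions (r = -0.37, Spearman's rho = -0.37). None of 100 relabellings of tanks within experiments gave a correlation as large (permutation p = 0.0099, the smallest they can give; adjusted p = 0.0594 over 6 pairs). Bifenthrin and cypermethrin had r = 0.23 (permutation p = 0.228), and the other 4 pairs lay between -0.11 and 0.045 (permutation p from 0.465 to 0.911). With the tank's spike-in level as a covariate, added after seeing the data, the correlation of bifenthrin and permethrin was 0.00228.

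The 2 concentrations of a chemical share their controls, so their changes correlate with no effect at all. The observed correlation was 0.709 for bifenthrin, 0.409 for cypermethrin, 0.487 for esfenvalerate and 0.606 for permethrin, against 0.503, 0.500, 0.316 and 0.497 for simulated unchanged groups. The covariance exceeded the simulated one by 0.115 for bifenthrin, 0.0124 for cypermethrin, 0.0241 for esfenvalerate and 0.0166 for permethrin. The simulation drew every probe independently, without variation that the probes of a tank share. It therefore gives no spread against which to judge these gaps, and no shared effect is concluded from them.

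The classifier did not separate exposed from control tanks. With 50 probes and 1 tank left out at a time, the area under the ROC curve over tanks was 0.314, and with 1 chemical left out 0.373. Permuted tank labels gave areas at least as large in 60 and 89 of 100 draws (permutation p = 0.604 and 0.891), with medians of 0.349 and 0.478. With 1 tank left out, bifenthrin 0.297 µg/L had an area of 1 against its own controls and cypermethrin 0.5 µg/L 0.667, and the other 6 concentrations had 0 to 0.333. With 1 chemical left out the first 2 had 0.333 and 0.778. Simulated arrays with 200 probes changed by 0.5 on the log2 scale, without differences between experiments, gave an area of 1. Leaving out 1 array at a time, so that arrays of a tank stood in training and test, raised the area to 0.516. With each experiment centred on its own controls, the area was 0.599 with 1 tank left out (0.722 for bifenthrin, 0.611 for cypermethrin, 0.222 for esfenvalerate and 0.667 for permethrin) and 0.365 with 1 chemical left out, without a permutation test. That centring also used the control tanks that were left out, so these areas are not fully held out.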

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

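The tests on the place of vessels, on exposure, on a batch of whole groups, on spike-in level for the bifenthrin count and the splits of tanks were chosen after the results they bear on were seen, and the spike-in covariate itself was added after seeing the data.

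The shared change of bifenthrin 0.297 µg/L and cypermethrin 0.5 µg/L is the first pattern. The values argue against slide, signal strength and vessel place for the sharing. With the slide as a block 14858 probes were called at bifenthrin 0.297 µg/L, against 13775 in the same fit without it. The shared calls were 2175 with the slide block and 1465 without it. With spike-in level as a covariate 848 shared calls stood, against 602 without. The lists also moved, from 822 to 1348 at cypermethrin 0.5 µg/L and from 13267 to 6700 at bifenthrin 0.297 µg/L. The groups that share the change stood in different vessels, 5, 23 and 26 for bifenthrin 0.297 µg/L and 14, 19 and 25 for cypermethrin 0.5 µg/L. Cypermethrin 1 µg/L, in the same vessel numbers as bifenthrin 0.297 µg/L, moved in the shared direction at only 65.8% of the 602 probes. That share uses the cypermethrin controls that helped choose the probes, which favours the shared direction. A level of these probes that only pyrethroid exposure gives is also argued against. The esfenvalerate controls, with 0 µg/L measured, differed from bifenthrin 0.148 and cypermethrin 1 µg/L in the changed direction at 99.7% of the shared probes. The median was 0.75 on the log2 scale. Of all other probes 64.1% also lay on the side of the bifenthrin 0.297 µg/L change in those controls. This comparison crosses experiments, whose carrier controls differed at 60.6% of probes, so it does not test the change within an experiment. A batch of rearing or RNA work that followed whole groups may be behind it: the largest gap between group means, which lies between cypermethrin 1 and permethrin 3.125 µg/L and so between groups that did not choose the probes, was 5.35 times the largest SD between tanks. Such a batch cannot be told apart from the groups, because no label records one. A mislabelled group was not tested and stays open, as does exposure that moved larvae along an axis on which unexposed cohorts also differ.

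The second pattern is the opposite direction of bifenthrin and permethrin, r = -0.37. The real split alone (1 of 101) reached that size, with 0.347 the highest other, but the adjusted p over 6 pairs was 0.0594, so chance is not excluded at the threshold of 0.05. Array signal strength is a candidate explanation, since with the spike-in level of each tank as a covariate the correlation was 0.00228. Spike-in level fell from control to exposed tanks in the bifenthrin experiment, by 0.61, adjusted p = 0.0476 by exact permutation. The size leans on control vessel 12, with 1 array, at -0.458. The other controls, at -1.40 and -1.33, still lay above every exposed tank, the highest at -1.46. It was higher by 0.50 in exposed permethrin tanks, adjusted p = 0.0714, which does not pass 0.05. The covariate cannot tell whether labelling or exposure changed the ratio of larval to spike-in signal.

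The third pattern is the number of probes that differed in the bifenthrin experiment. With the spike-in covariate 6700 probes were called at 0.297 µg/L, between the bounds set for and against signal strength (of the 13267 called without it), so its share cannot be told apart from exposure. For the mean of both concentrations the covariate took 9264 to 1076, a larger loss. No biological explanation was tested beyond the concentrations themselves.

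The shares of splits below are not adjusted over the comparisons. For 3 tanks against 3 the 10 splits are too few. At bifenthrin 0.297 µg/L the real split gave 13267 and the highest other 1, at cypermethrin 0.5 µg/L 822 and 2, and at cypermethrin 1 µg/L 7 and 40, so 2 of 10 reached the real count. Higher minus lower gave 3556 against 0 for bifenthrin and 1233 against 1 for cypermethrin, in each case 1 of 10. Comparisons with 0 calls are matched by every split, 10 of 10 or 100 of 100, which tests nothing; their highest others were 4 at bifenthrin 0.148 µg/L, 552 for the alpha-cyano contrast, 8 for esfenvalerate against permethrin, 2 for the permethrin mean and 0 for the other permethrin comparisons. Taken alone, and before any adjustment, the share is under 0.05 for the bifenthrin mean (1 of 100, 9264 against 3081) and the carrier controls (1 of 100, 26569 against 18411). For the mean of 4 chemicals 2 of 100 splits reached the 21, the real one included, but another called 1066, and the 21 are not taken as beyond chance. Chance cannot be excluded for the cypermethrin mean (7 of 100, 31 against 758) or the esfenvalerate mean (22 of 60, 4 against 44). Splits that call many more probes than the real one point to a structure of the tanks. Which tanks they regrouped was not examined, so that structure can be the exposure groups themselves.

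Effects of chemicals differed by their own test at 38 probes between bifenthrin and cypermethrin, 717 between bifenthrin and esfenvalerate, 6489 between bifenthrin and permethrin, 5 between cypermethrin and esfenvalerate and 8 between cypermethrin and permethrin. Relabelled tanks reached these counts in 3, 2, 2, 2 and 3 of 100 splits, the real one included, with highest others of 7160, 2613, 8414, 6 and 3968. At matched nominal concentrations cypermethrin and esfenvalerate differed at 68 probes at 0.5 µg/L and 8 at 1 µg/L, without a count of splits because esfenvalerate had 2 and 1 tanks.

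Single arrays lay far from the others of their group in 8 of the 33 pairs of measure and group tested, where chance gives about 1 in 20. The 75th percentile of signal was 1910 in replicate 3 of cypermethrin 0.5 µg/L (others up to 1220), 2200 in replicate 4 of the permethrin controls (others up to 1350) and 1610 in replicate 11 of permethrin 3.125 µg/L (others up to 1000). Probes well above background made up 64.6% in replicate 1 of bifenthrin 0.148 µg/L (others from 81.4%), 69.1% in replicate 6 of cypermethrin 0.5 µg/L (others from 80.9%) and 47.4% in replicate 10 of the permethrin controls (others from 71.9%). Spike-in level was -0.747 in replicate 9 of the cypermethrin controls (others up to -1.67) and -3.1 in replicate 3 of cypermethrin 0.5 µg/L (others from -2.14).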

How the results depend on the processing

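The spike-in covariate, the removal of arrays under 60% of probes well above background and the mean without bifenthrin 0.297 and cypermethrin 0.5 µg/L were chosen after the results were seen. Of 294 counts under alternatives that leave out no tank, 191 lay within 1.5 times the main count, and of 204 counts with a tank left out, 132. A count of 0 in both the main fit and the alternative was taken as within. Several comparisons had a main count of 0, so these shares overstate how stable the other counts were. Of 189 other values 174 were the same within the tolerance set. Each correlation except that of bifenthrin and cypermethrin changed sign in 1 or more settings, and those that moved furthest are given below. Over 50 alternatives each, SINGLET_6057 passed the threshold in 44, UF_Ppr_AF_100015 in 40, UF_Ppr_AF_115657 in 29 and SINGLET_12718 in 21, with adjusted p up to 0.77, 0.785, 0.744 and 0.752.

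Arrays with failed checks included gave 5213 for bifenthrin 0.297 µg/L, 1803 for cypermethrin 0.5 µg/L, 5 for esfenvalerate 1 µg/L, 1744, 1892 and 2 for the means of bifenthrin, cypermethrin and esfenvalerate, 695 and 207 for higher minus lower bifenthrin and cypermethrin and 3 for all pyrethroids. The correlation of cypermethrin and esfenvalerate was 0.232, against -0.0757. Normexp gave 8512 for bifenthrin 0.148 µg/L, 1501 and 4 for cypermethrin 0.5 and 1 µg/L, 4 for esfenvalerate 1 µg/L, 18008 and 181 for the means of bifenthrin and cypermethrin, 1656 and 725 for higher minus lower and 49 for all pyrethroids. Its correlations were 0.526 for bifenthrin and cypermethrin, -0.516 for bifenthrin and permethrin and -0.284 for cypermethrin and permethrin. Quantile normalization gave 16 for bifenthrin 0.148 µg/L, 27 for esfenvalerate 1 µg/L, 1 for higher minus lower esfenvalerate and 39 for all pyrethroids. The authors' table gave 0 for cypermethrin 1 µg/L, 21 for esfenvalerate 1 µg/L, 62 for all pyrethroids and 13 for cypermethrin minus esfenvalerate, and the stricter filter 0 for cypermethrin 1 µg/L.

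With tanks ignored 2 were called for bifenthrin 0.148 µg/L, 2333 for cypermethrin 0.5 µg/L, 2 for esfenvalerate 1 µg/L, 84, 0 and 830 for the means of cypermethrin, esfenvalerate and permethrin, 8972, 4112 and 8 for higher minus lower bifenthrin, cypermethrin and esfenvalerate, 181 for all pyrethroids and 20 for cypermethrin minus esfenvalerate, with correlations of -0.244 for cypermethrin and esfenvalerate and -0.28 for cypermethrin and permethrin. In the same order, without bifenthrin 0.148 µg/L, the tank as a random block gave 1986, 2, 74, 0, 389, 8362, 3630, 1, 135 and 0, with -0.239 and -0.276. The slide block gave 2657, 3, 86, 0, 142, 9378, 4842, 1, 282 and 0, and 0 for cypermethrin 1 µg/L. The replicate block gave 1963, 3, 73, 0, 1123, 7894, 3560, 10, 125 and 0, with 3 for cypermethrin 1 µg/L, 4 for permethrin 1.56 µg/L and -0.289 for cypermethrin and permethrin. Replicate numbers do not pair samples, so this block tests nothing further.

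Tank means weighted by arrays gave 1 each for cypermethrin 1 and permethrin 1.56 µg/L, 5121 and 0 for the means of bifenthrin and esfenvalerate, 6653 and 2539 for higher minus lower bifenthrin and cypermethrin and 18 for cypermethrin minus esfenvalerate, with -0.244 and -0.281. Each experiment alone gave 5004 for the bifenthrin mean, 1220 and 95 for higher minus lower bifenthrin and cypermethrin, 42 and 0 for cypermethrin 0.5 and 1 µg/L, 0 for its mean, 5 for esfenvalerate 1 µg/L and 0 for its mean. Deaths as a covariate gave 0 for cypermethrin 1 µg/L, 7 for esfenvalerate 1 µg/L and 429 for higher minus lower cypermethrin. Slopes on measured concentration gave 0 for cypermethrin and 9 for esfenvalerate. The spike-in covariate gave 6700 for bifenthrin 0.297 µg/L, 1348 for cypermethrin 0.5 µg/L, 1076 and 10 for the means of bifenthrin and esfenvalerate, 73 for all pyrethroids, 12 for cypermethrin minus esfenvalerate and a correlation of 0.00228 for bifenthrin and permethrin. Without arrays under 60% of probes well above background the counts were 0 for cypermethrin 1 µg/L, 5 for esfenvalerate 1 µg/L, 0 for its mean, 12 for all pyrethroids and 3 for cypermethrin minus esfenvalerate. Without bifenthrin 0.297 and cypermethrin 0.5 µg/L, all pyrethroids gave 0.

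Leave-one-out over tanks, and over arrays of esfenvalerate 1 µg/L, whose lone tank is assumed to vary like the other groups, gave 0 to 1579 for bifenthrin 0.148 µg/L, 6515 to 13768 for bifenthrin 0.297 µg/L, 633 to 10493 for its mean, 1184 to 4233 for higher minus lower, 350 to 694 and 0 to 107 for cypermethrin 0.5 and 1 µg/L, 10 to 168 for its mean and 412 to 994 for higher minus lower. It gave 0 to 3 and 4 to 132 for esfenvalerate 0.5 and 1 µg/L, 0 to 15 for its mean, 0 to 12 for higher minus lower (2 without vessel 10, 12 and 11 without replicates 2 and 3), 1 to 156 for all pyrethroids, 0 to 2 for the alpha-cyano contrast (2 without cypermethrin control vessel 12) and 3 to 53 for cypermethrin minus esfenvalerate. The last was 3 without cypermethrin control vessel 17, vessels 19, 25, 5 or 23 of exposed cypermethrin, esfenvalerate control vessel 17 or vessels 10 or 18, 53 and 11 without cypermethrin control vessels 9 and 12, 10 without esfenvalerate control vessel 12, and 18 and 9 without replicates 2 and 3. Correlations ran from 0.036 (without cypermethrin control vessel 17) to 0.377 (without vessel 9) for bifenthrin and cypermethrin, and from -0.351 (without vessel 9) to 0.137 (without vessel 17) for cypermethrin and permethrin. The 2 gene-list alternatives were not run, for lack of gene names. Array-level fits were not run for the classifier.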

Other observations

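These counts and correlations were looked at after the results were seen. The 12 probes lower at esfenvalerate 1 µg/L shared 4 members with those called at cypermethrin 0.5 µg/L, in the opposite direction, against 0.0878 for independent lists, and the 7 called at cypermethrin 1 µg/L shared none with the calls at bifenthrin 0.297 µg/L. Probes called at bifenthrin 0.297 µg/L had the same sign at cypermethrin 0.5 µg/L in 84.4% of cases, at cypermethrin 1 µg/L in 52.3%, at esfenvalerate 1 µg/L in 39.6% and at permethrin 3.125 µg/L in 29.8%.

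Over all 43876 probes, the change at bifenthrin 0.297 µg/L correlated with the change at cypermethrin 0.5 µg/L at r = 0.431, and with the difference of permethrin controls from cypermethrin 1 µg/L, where no tank is shared, at r = 0.419, but with the same difference for esfenvalerate controls at r = 0.158. The change at cypermethrin 0.5 µg/L correlated with the differences of esfenvalerate and permethrin controls from bifenthrin 0.148 µg/L at r = 0.412 and 0.362. Probes are not independent replicates. Of the 100 joint splits of tanks within the bifenthrin and cypermethrin experiments 3 gave a correlation of at least 0.431 in size, the real one included. The others of these lay at 0.434 or above, so the real split was not the largest.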
